A study of Rattus norvegicus with 8 samples.

How the data were processed

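Poly-A RNA from whole testis of Holtzman Sprague-Dawley rats at postnatal day 60 was sequenced in 4 Taf7l knockout and 4 wild-type samples, per the labels. The sources used here do not say which part of the gene the knockout removes, nor whether the samples of a group came from separate animals, so p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample titles, and each library's columns were matched by genotype and replicate number.

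The deposited table holds 31215 genes with Ensembl identifiers. Per the file headers, it gives read counts for each gene and library: total exon reads, exon reads placed at 1 position only, intron reads, gene reads (exon plus intron) and reads across exon junctions. The deposited RPKM values are total exon reads scaled by exon length and by mapped reads, per the file headers, and the same library total came back from every gene. The authors also deposited a comparison of the groups, with a p-value and a false discovery rate per gene from a test with tagwise dispersions, per the file headers. The authors' signed fold change in that table is a score that is negative where the knockout is lower. The aligner and counting tool are not given in the sources used here. The submitters' processing notes name the Rnor 5.0 assembly, but 6446 genes carry contig names starting with AABR07, and annotated genes on X reach position 159891326, which fit a later assembly. The build is therefore unsettled, and coordinates are given as the table has them. RefSeq gene names served only to match synonyms.

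Total exon reads were analysed as counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to the group alone. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size. No column of per-sample values was left without a sample (0 such columns).

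A set of 28 gene lists, covering testis cell types, TFIID and other pathways, was fixed before the data were examined. Of 488 list entries, 461 were found by symbol and 5 by synonym, and 22 are not analysed here. Taf7l is in no list. Lists share members, and 21 tested genes are in more than one, among them Taf4b, Tbpl1, Tex11, Scml2, Acrbp and Zpbp2, so their results are not independent. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. The mean log2(CPM + 0.5) of each cell type list per library was compared by an exact two-sided permutation test, whose smallest p with 4 libraries per group is 0.0286. The share of called genes on X was compared with autosomes by Fisher's exact test, which counts genes and does not measure the spread between samples. Single measures per library were compared by the same exact permutation test.

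Genes named in the text follow a rule fixed before the data were examined. It takes Taf7l and every TFIID list member past the threshold. It adds the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, with a mean of at least 5 CPM in the higher group and a symbol that is no placeholder. It also takes the 3 members of each list with the smallest p, of which 2 genes are not used here. Other list members named as further examples, and the genes of the closing observations, were chosen after their values were seen.

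The alternatives planned before the data were examined were RLE factors, library size alone, no filter on low counts, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p below 0.01, a test against a 1.5-fold change, camera with an estimated correlation, fry, and, for chromosomes, genes of at least 5 CPM. A pseudocount alternative applied only to normalised values and was not used. Unique exon reads, total gene reads and scaling to the Sertoli cell list were added after seeing the data. Whether the replicate numbers pair the samples is treated with the other alternatives.

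Scripts were tested on simulated counts for the 15712 genes of this comparison, with 200 genes changed. The quasi-likelihood test recovered 44 of 60 genes changed 1.5-fold, 69 of 70 changed 2-fold and 70 of 70 changed 4-fold, and called 10 of 15512 unchanged genes. Both groups were drawn from the wild-type means at a common dispersion, with changes divided evenly between directions. The real comparison called 14246 genes, so these rates hold for few, balanced changes and may not carry over to it. Same-group libraries differed by more than sampling noise, with chi-square values per gene from 3.31 to 37.0. Each was counted as its own sample, though such variation does not show that the samples came from separate animals. Exon reads ranged from 15.7 M to 23.7 M per library. Intervals on shares are exact binomial 95% intervals that cover counting error only.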

Results

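Whole testis of Taf7l knockout and wild-type rats was profiled at postnatal day 60 to ask how loss of this X-linked TFIID subunit, a germ cell paralog of Taf7, alters the adult testis transcriptome. There were 4 libraries per genotype. Exon reads numbered 23.3 M, 23.7 M, 20.8 M and 23.6 M in wild-type replicates 1 to 4 and 15.7 M, 21.5 M, 17.5 M and 20.5 M in knockout replicates 1 to 4. Mitochondrially encoded transcripts took 2.16% ± 0.055 of exon reads in the wild type and 7.81% ± 0.423 in the knockout (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0317 over 10 library measures). Intron reads took 14.5% ± 1.40 and 20.8% ± 0.833 of gene reads (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0317).

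The targeted gene was examined first. Taf7l (ENSRNOG00000026315, chromosome X, 105292337 to 105308554, 12 exons, build unsettled) kept reads in every library. Its exon level was 28.8, 29.6, 33.5 and 31.0 CPM in wild-type replicates 1 to 4 and 21.4, 17.2, 23.6 and 21.1 CPM in knockout replicates 1 to 4. The log2 fold change was -0.56 (SE 0.096, adjusted p = 1.6e-04, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), but it turned to 0.23 when libraries were scaled by size alone and to 0.46 when intron reads were added. It was -0.71 with RLE factors and -2.45 with libraries scaled to the Sertoli list. Relative to the median of all tested genes it was -0.74 with TMM and with library size. The deposited RPKM of Taf7l was 9.22 ± 0.629 in the wild type and 10.02 ± 1.21 in the knockout (SD, n = 4 each; exact permutation p = 0.314). In the authors' deposited table its signed fold change was -1.40 with a false discovery rate of 0.525. Exon reads alone therefore did not separate the genotypes under every scaling, and the removed part of the gene is not given in the sources used here.

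Intron reads of Taf7l did separate them. They made up 12.6, 13.8, 14.3 and 9.83% of the gene's exon and intron reads in wild-type replicates 1 to 4 and 53.7, 56.1, 54.6 and 54.1% in knockout replicates 1 to 4. The group means were 12.6% ± 2.00 and 54.6% ± 1.05 (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0317). The exact binomial 95% intervals of single libraries ran from 7.57% to 17.3% in the wild type and from 50.5% to 59.0% in the knockout.

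**Figure D1:**
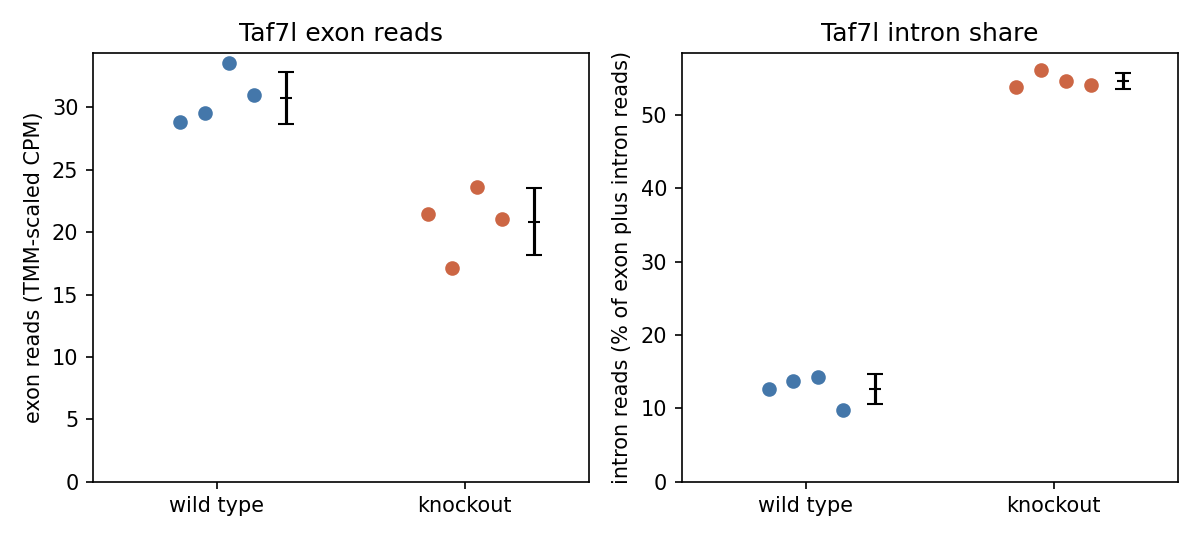
Taf7l exon reads (TMM-scaled CPM, left) and intron reads as a percentage of exon plus intron reads (right) in each of 4 wild-type and 4 knockout libraries, with bars for mean and SD. Exon levels averaged 30.7 CPM and 20.8 CPM, an order that turned when libraries were scaled by size alone, and intron shares averaged 12.6% and 54.6%.

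The main comparison asked which transcripts differed between knockout and wild-type testis. Transcripts of late pachytene spermatocytes and spermatids fell under every scaling, with list medians from -3.67 to -3.18 with TMM and from -2.87 to -2.38 with library size alone, while those of Sertoli cells took a larger share. The acrosomal gene Zpbp2 fell from 139 ± 6.58 to 10.9 ± 0.299 CPM, and Clu, a secreted Sertoli cell product, rose from 1041 ± 46.7 to 5792 ± 189 CPM (SD, n = 4 each). Of 15712 genes tested, 7578 were higher and 6668 lower in the knockout at an adjusted p below the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg). More than 4-fold changes were seen in 1970 higher and 2889 lower genes. The split depended on scaling: with library size alone 9776 were higher and 4656 lower, and with libraries scaled to the Sertoli list 1037 were higher and 11922 lower. The median log2 fold change of all tested genes was 0.18 with TMM, 0.03 with RLE factors, 0.98 with library size alone and -1.71 with Sertoli scaling, so list medians are also given relative to that median. In the authors' deposited comparison, 3207 genes were higher and 4239 lower at a false discovery rate below 0.05, and 7430 of the 7436 such genes tested here were also called here, all in the same direction.

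The largest rise was that of Wnt4, a secreted signalling factor, from 2.54 ± 2.97 to 166 ± 16.5 CPM (SD, n = 4 each; log2 fold change 6.08, SE 0.50, adjusted p = 1.2e-05, edgeR quasi-likelihood). Wild-type replicate 3, at 6.98 CPM of Wnt4, stood above the other wild-type libraries (0.845 to 1.38 CPM), and the log2 fold change was 7.24 without it. Testin, a secreted product of Sertoli cells, rose by a log2 fold change of 4.56, from 1.74 to 40.4 CPM. The other large rises were Rd3l (4.41), Scn3b (4.32), Ssh3 (4.10), Tnfrsf12a (4.07), Mybphl (3.89), Aldh1a7 (3.85), Trim47 (3.83), Lpl (3.80), the endothelin gene Edn1 (3.66) and the ephrin receptor Epha2 (3.65). For Lpl, lipoprotein lipase, the size of the rise rested on knockout replicate 2, at 28.3 CPM against 1.42 to 3.13 CPM in the other knockout libraries. Without that library the log2 fold change of Lpl was 1.86 and Lpl was still called. The largest falls were Itprid1 (-4.72), Strc (-4.58), Zfp353 (-4.57), Glipr1l1 (-4.52), Tpte2 (-4.41), Stkld1 (-4.39), Tmem190 (-4.38), Lmod2 (-4.38), Fam131a (-4.35), Gcnt3 (-4.35), Fam47a (-4.33) and Nipsnap3a (-4.31). Only 14.1% of Lmod2 exon reads and 0% of those of Fam131a were placed at 1 position, so these values are uncertain.

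Germ cell lists were compared to place the difference along spermatogenesis. Among markers of undifferentiated spermatogonia, 12 of 15 tested members were higher and 2 lower, the same 12 and 2 when adjusted over the list alone, with a median log2 fold change of 1.59 (1.41 relative to all genes). Foxo1 rose (1.88) and Id4 fell (-1.54), and the list did not pass camera (adjusted p = 0.13). Among markers of differentiating spermatogonia, 11 of 12 were higher and 1 lower, and 11 and 1 adjusted over the list alone, with a median of 1.98 (1.80 relative to all genes). The receptor Kit rose from 17.1 to 71.1 CPM and Crabp1 from 4.63 to 29.7 CPM, while Dmrtb1 fell from 143 to 21.4 CPM. This list passed camera (adjusted p = 0.0066), with adjusted p = 0.13 with an estimated correlation. Its rise depended on scaling: the median was 0.09 with libraries scaled to the Sertoli list. Relative to the Sertoli level, the mean level of the list changed by -0.42 (exact permutation test, adjusted p = 0.0391).

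Early meiotic prophase genes went both ways. Of 31 tested, 15 were higher and 12 lower, likewise adjusted over the list alone. The cohesin genes Rec8 (-2.85) and Smc1b (-1.51) and the recombination factor Psmc3ip (-2.41) fell, whereas Mei4 (2.14), Rad21l1 (2.08), Tex11 (2.08) and the recombinase Dmc1 (1.39) rose. Mei4 was near the floor, at 0.22 CPM in the wild type and 1.02 CPM in the knockout (SE 0.51). The median was 0.10, the mean 0.03 and the camera direction lower (adjusted p = 0.86), and the median was 0.89 with library size alone but turned to -0.05 with RLE factors and to -1.80 with Sertoli scaling. Late pachytene and diplotene genes fell in 16 of 17 cases and rose in 1, likewise adjusted over the list alone, with a median of -3.18 (-3.36 relative to all genes, camera adjusted p = 3.6e-08, adjusted p = 0.11 with an estimated correlation). Hspa2, a chaperone of meiotic spermatocytes, fell from 3698 to 336 CPM and Insl6 from 114 to 8.58 CPM.

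Spermatid transcripts fell throughout the lists. All 26 tested round spermatid genes were lower, with a median of -3.67 (-3.85 relative to all genes, camera adjusted p = 9.2e-17, adjusted p = 0.074 with an estimated correlation), and all 28 elongating spermatid genes were lower, with a median of -3.47 (-3.65 relative to all genes, camera adjusted p = 0.0031, adjusted p = 0.70 with an estimated correlation). Counts adjusted over the list alone were again 26 and 28. Acrbp fell from 509 to 42.7 CPM, Spaca3 from 96.8 to 6.79 CPM and Actl7b from 761 to 50.8 CPM. The linker histone Hils1 fell by 3.46 and Cylc2 by 3.43 on the log2 scale. All 21 flagellum genes (median -3.60), all 21 acrosome and fertilisation genes (median -3.54) and all 12 sperm energy genes (median -3.30) were lower, also adjusted over the list alone. Examples were Cfap44 (-3.80), Tekt3 (-3.78), Ropn1l (-3.19), Dcst1 (-4.09), Gk2 (-3.74), Cox8c (-3.30) and Cox6b2 (-2.84). The flagellum (camera adjusted p = 2.4e-15) and acrosome lists (camera adjusted p = 9.2e-17) each kept an adjusted p = 0.019 with an estimated correlation, and the sperm energy list (camera adjusted p = 4.6e-05) had adjusted p = 0.13 with an estimated correlation.

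Somatic cell lists moved the other way. Among Sertoli cell markers 21 of 22 tested were higher and 0 lower, likewise adjusted over the list alone, with a median of 2.08 (1.90 relative to all genes, camera adjusted p = 1.2e-08, adjusted p = 0.021 with an estimated correlation). Besides Clu, Shbg rose from 54.4 to 296 CPM and Cst12 from 46.7 to 206 CPM, and the X-linked homeobox gene Rhox5 did not pass (log2 fold change -0.33). Leydig cell genes were higher in 14 of 16 cases and lower in 1, likewise adjusted over the list alone, with a median of 2.13 and with Nr5a1 (2.23), Tspo (2.89) and Hsd11b1 (2.13) among them (camera adjusted p = 0.0056, adjusted p = 0.50 with an estimated correlation). All 10 peritubular and smooth muscle genes (Myl9 1.89, Mylk 1.25, Lmod1 1.88, camera adjusted p = 0.025, adjusted p = 0.64 with an estimated correlation) and all 9 fibroblast genes (Sparc 2.36, Pdgfra 2.43, Fbln1 1.95, camera adjusted p = 0.018, adjusted p = 0.52 with an estimated correlation) were higher, also adjusted over the list alone. On the Sertoli scale the medians of peritubular genes (-0.32), macrophage genes (-0.0035), lymphocyte genes (-0.56), endothelial genes (-0.62) and undifferentiated spermatogonia (-0.27) turned negative. Of 116 named genes 23 turned on that scale, among them Foxo1, Myl9, Mylk, Lmod1, Csf1r, Cd4, Cdh5, Vwf, Tie1, Hba-a1, Hbb, Pparg, Cebpa and Jun.

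Blood and vessel lists were mostly higher without passing camera. Macrophage genes were higher in 12 of 14 cases and lower in 2 (Csf1r 1.87, C1qc 2.02, Cd68 1.90, camera adjusted p = 0.090), endothelial genes in 9 of 10 (Cdh5 1.39, Vwf 1.45, Tie1 1.32, camera adjusted p = 0.30), and lymphocyte genes in 5 of 8 with 3 lower (Cd79a 2.61, Cd4 1.83, Cd3e 2.63, camera adjusted p = 0.33). Adjusted over the list alone the counts were the same. Erythroid genes were higher in 4 of 4 cases (Alas2 1.98, Hba-a1 1.77, Hbb, 1.67), too few for camera. Knockout replicate 2 held more of both globin transcripts, and without it the log2 fold change was 1.17 for Hba-a1 and 1.12 for Hbb. Adipocyte genes were higher in 6 of 8 cases and lower in 1 (Cfd 2.25, Pparg 1.46, Cebpa 1.82, camera adjusted p = 0.45), with a list mean of 3.49 in knockout replicate 2 against 1.70 to 1.82 in the other knockout libraries, and no epididymis gene passed the filter (0 tested). In the library means of the 15 cell type lists with tested members, 14 differed between genotypes (exact permutation test, adjusted p = 0.0306) and early meiotic prophase did not (adjusted p = 0.657), though it did with RLE factors, lower, and with library size alone, higher (adjusted p = 0.0286 each).

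**Figure D2:**
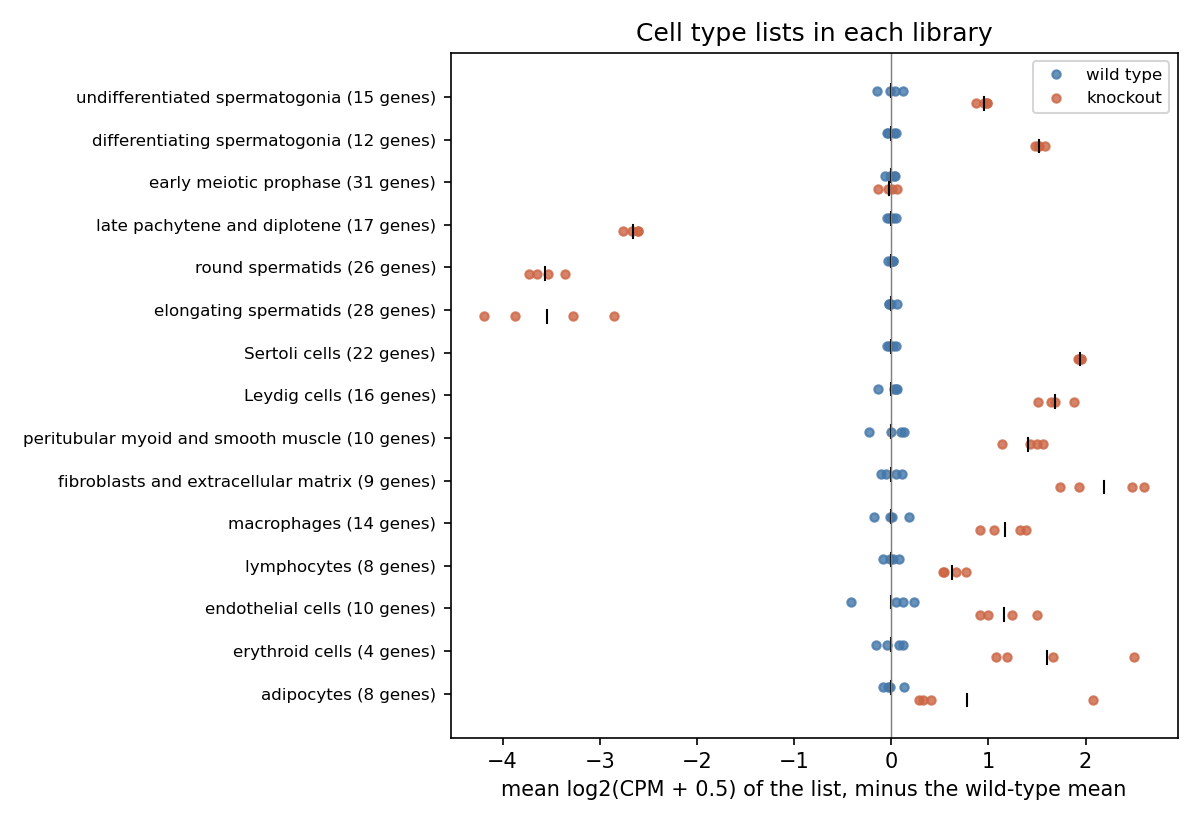
Mean log2(CPM + 0.5) of each cell type list in 4 wild-type and 4 knockout libraries, minus the wild-type mean, with vertical ticks for group means. Round spermatid lists lay 3.57 below and Sertoli lists 1.94 above the wild type with TMM scaling. The sign of several lists depended on scaling. Relative to the Sertoli level, the mean Leydig level was 0.26 lower (exact permutation test, adjusted p = 0.0675). The median Leydig log2 fold change on the Sertoli scale went the other way, at 0.23. Neither value is plotted.

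TFIID and its paralogs were compared because Taf7l belongs to this complex. The list also held Gtf2a1 and its paralog Gtf2a1l, which encode subunits of TFIIA, and Gtf2b, which encodes TFIIB, so these genes are not TFIID members. Of 18 tested members, 7 rose and 11 fell, likewise adjusted over the list alone, and the list did not pass camera (adjusted p = 0.082). The germ cell paralogs fell with the late germ cell genes: Gtf2a1l from 472 to 34.8 CPM (-3.76) and Tbpl1 from 222 to 31.5 CPM (-2.81). Tbp (-2.69), Taf9 (-2.89), Taf12 (-1.18), Taf5 (-1.02) and Taf6 (-0.95) also fell, as did Taf10 from 303 to 75.7 CPM. The genes that rose were the spermatogonial paralog Taf4b (1.36), the X-linked Taf9b (1.34), Taf4 (0.96), Taf13 (0.79), Taf7 (0.68), Taf11 (0.47) and Taf2 (0.40), but all 7 turned on the Sertoli scale, to -0.53, -0.56, -0.93, -1.11, -1.21, -1.43 and -1.49 in the same order. Taf8 (-0.40), Gtf2a1 (-0.32) and Gtf2b (-0.22) fell with TMM but turned to 0.39, 0.47 and 0.58 with library size alone. Only 26.6% of Taf9 exon reads were placed at 1 position. The list median was -0.36 (-0.54 relative to all genes) and turned to 0.43 with library size alone.

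Among the other pathway lists, piRNA genes fell in 19 of 22 cases and rose in 2 (Mael -2.69, Tdrd6 -3.95, Tdrd7 -2.44, camera adjusted p = 7.2e-04, adjusted p = 0.23 with an estimated correlation). X-linked premeiotic germ cell genes rose in 8 of 10 cases and fell in 2 (Usp26 2.07, Scml2 2.34, Tex11 2.08, camera adjusted p = 0.044, adjusted p = 0.64 with an estimated correlation). Cholesterol synthesis genes went both ways, 10 higher and 8 lower of 19, with Fdft1 (-1.80) and Fdps (431 to 108 CPM) lower (camera adjusted p = 0.58), and the median of 0.29 turned to -1.60 on the Sertoli scale. Of 14 p53 and apoptosis genes 11 rose and 2 fell, with Cdkn1a (1.85) and Sesn1 (1.42) higher and Mdm2 (-2.42) lower (camera adjusted p = 0.15), but on the Sertoli scale the median of 1.26 turned to -0.63, Cdkn1a to -0.0364 and Sesn1 to -0.47. Interferon and inflammation genes rose in 15 of 16 cases and fell in 1 (Irf9 1.97, Cxcl10 2.74, camera adjusted p = 0.32), with a median of 1.86 that turned to -0.0244 on the Sertoli scale. Immediate early and handling stress genes, listed as a check of sample quality, rose in 10 of 12 cases and fell in 1 (Jun 1.73, Zfp36 2.55, Dnajb1 -2.35, camera adjusted p = 0.68), and the list mean varied between knockout libraries (5.20, 5.73 and 4.79 in replicates 1 to 3, with replicate 4 close to the highest wild-type library at 3.52). Cell cycle genes rose in 7 and fell in 11 of 18 cases (Mcm2 2.27, Ccnb1 -2.56, Pcna -1.59, camera adjusted p = 0.68), and oxidative phosphorylation genes rose in 6 and fell in 12 of 18 (Uqcrfs1 -2.23, Cox5b -1.19, Ndufs1 -0.86, camera adjusted p = 0.37), and the medians of both lists, -0.57 and -0.55, turned to 0.23 and 0.25 with library size alone. Counts adjusted over the list alone were the same for each of these lists. In total 13 of 26 lists passed camera, 6 higher and 7 lower, and 3 passed with an estimated correlation.

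Genes on the X chromosome were compared with autosomal genes because Taf7l is X-linked and X is silenced in male meiosis. X-linked genes were more often higher: 434 of 615 tested (70.6%) against 7105 of 15033 autosomal genes (47.3%), an odds ratio of 2.68 (95% interval 2.24 to 3.21, Fisher's exact test, p = 3.0e-30). They were less often lower, 146 (23.7%) against 6504 (43.3%), an odds ratio of 0.41 (Fisher's exact test, p = 4.3e-23). Fisher's test treats genes as independent units, so these p-values and the interval do not measure the spread between samples. Among them Taf9b, Usp26, Scml2, Tex11 and Alas2 rose and Fam47a fell. The median log2 fold change was 1.60 on X and 0.13 on autosomes.

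**Figure D3:**
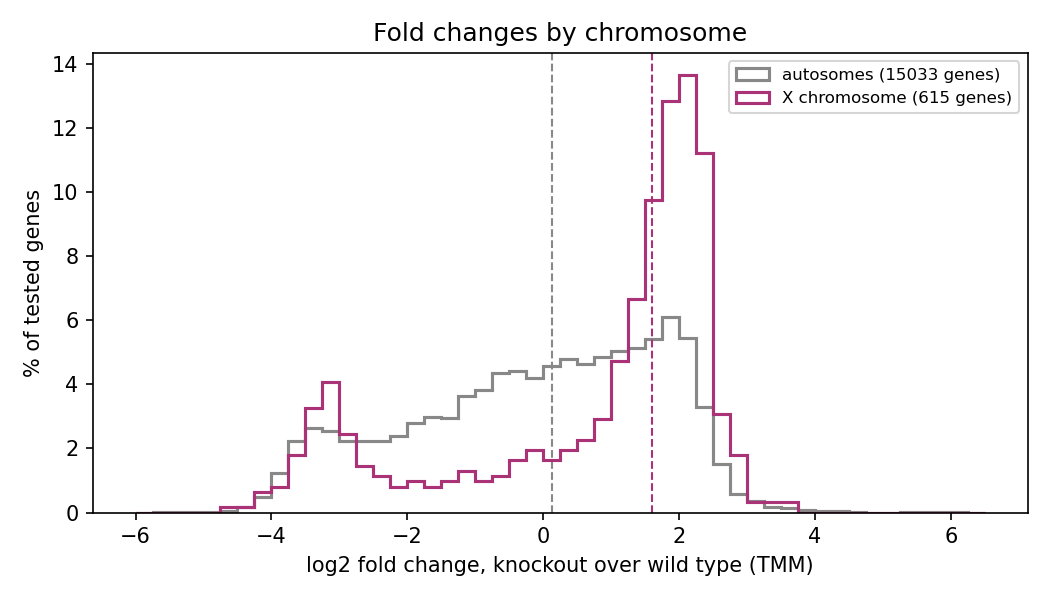
Log2 fold changes (knockout over wild type, TMM) of 615 X-linked and 15033 autosomal genes as a percentage of tested genes in each class, with dashed lines at the medians of 1.60 and 0.13. Both classes have a group of genes at strongly negative values.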

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

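The tests of this part, except the count of sample splits, were chosen after the result was seen.

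Of 302 groups of 4 libraries examined, 14 held a library far from the other 3, where chance gives about 15.1, so the number of such values is no more than chance. Intron reads were outside the main measurement and stood above the wild type for Taf7l.

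The knockout libraries held 54.6% intron reads for Taf7l, against 9.83% to 14.3% in the wild type, a rise of 41.95 percentage points. A library-wide rise of intron reads was argued against: the rise lay at percentile 99.963 of 5405 genes with a steady exon level, whose median rise was 4.24 points. A rise of intron reads shared by premeiotic germ cell genes was also argued against, since 32 genes of those lists had a median change of -1.73 points (SD 10.9, highest 7.01). That test measured a change between genotypes and not the intron share itself. It therefore cannot exclude that RNA of premeiotic germ cells is incompletely spliced in both genotypes, with more of the Taf7l reads coming from those cells in the knockout. A transcript altered by the mutant allele may remain as a hypothesis, and it was not tested because the table does not place reads within the gene.

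Knockout replicate 2 had a mean log2 level of 3.49 for the adipocyte list against 1.70 to 1.82 in the other knockout libraries, and 28.3 CPM of Lpl against 1.42 to 3.13. Scaling of that library was argued against, because its Sertoli list level differed from the other knockout libraries by -0.0236 where the adipocyte list differed by 1.74. Adipose tissue in the sample may explain it, but the test did not decide: 6 of 8 members were highest in that library, below the 7 set for that explanation, and Cfd and Pparg were not. Fabp4 stood at 16.9 CPM against 0.768 to 1.20 CPM, while Adipoq (9.36 CPM) was at a level the wild type also showed (7.27 to 10.5 CPM) and Cidec (4.51 CPM) was below every wild-type library (5.67 to 7.55 CPM). The same library was also the highest knockout for erythroid (6.36 against 4.94 to 5.53), fibroblast (7.03), Leydig (5.84), endothelial (3.72), lymphocyte (2.27) and immediate early lists (5.73), which were no part of the adipose tissue test, and a cause within the testis was not tested.

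Other values far from their group were the Leydig cell list level of 3.82 in wild-type replicate 4 (others 3.99 to 4.02) and 20.8 M exon reads in wild-type replicate 3 (others 23.3 M to 23.7 M). In wild-type replicate 3, Wnt4 stood at 6.98 CPM (others 0.845 to 1.38) and Mybphl at 0.692 CPM (others 0.275 to 0.286). In wild-type replicate 4, Zfp353 stood at 6.02 CPM and Hsd11b1 at 35.5 CPM, in wild-type replicate 1 Cst12 at 46.1 CPM, and in wild-type replicate 2 Cox6b2 at 356.9 CPM. In knockout replicate 1, Taf4b stood at 41.8 CPM and Rec8 at 18.5 CPM, and in knockout replicate 2 Clu at 5511 CPM and Vwf at 38.6 CPM.

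Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many changed genes (1 of 35). That is the smallest share that 35 splits can give (0.0286), so the count cannot exclude chance beyond it. Every other split mixes the genotypes within a group, which raises its spread and makes few calls likely. The real split called 14246 genes and the highest of the other splits 0 with edgeR, where at most 204 genes had an unadjusted p below 0.05.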

How the results depend on the processing

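Alternatives marked as added were chosen after seeing the data. The count of 14246 changed genes stayed within 1.5 times under each alternative run, from 11540 when tested against a 1.5-fold change to 16349 with total gene reads (added), and from 14153 to 14294 when any 1 library was left out. Scaling to the Sertoli list (added) gave 1037 higher and 11922 lower genes and 9 cell type lists past the test. It sets the mean log2 level of that list to a common value in every library, and the median of the list was still 0.19. Taf7l turned to 0.23 with library size alone and to 0.46 with total gene reads, which add its intron reads, and ranged from -0.63 to -0.48 when any 1 library was left out. With library size alone, Gtf2a1 (0.47), Gtf2b (0.58) and Taf8 (0.39) turned, as did the camera direction of early meiotic prophase (adjusted p = 0.995), immediate early genes (0.683), cell cycle (0.923) and oxidative phosphorylation (0.980), while peritubular and fibroblast genes (each 0.0808), X-linked premeiotic genes (0.0672) and Ndufs1 (0.129) lost their calls. Gtf2b (0.0409) and the camera direction of early meiotic prophase (0.746) also turned with total gene reads, where Taf8 (-0.108) lost its call (edgeR adjusted p = 0.207). The early meiotic median was -0.0499 with RLE factors. On the Sertoli scale these medians turned: undifferentiated spermatogonia -0.27, early meiotic prophase -1.80, peritubular -0.32, macrophages -0.0035, lymphocytes -0.56, endothelial -0.62, erythroid -0.10, adipocytes -0.13, cholesterol synthesis -1.60, p53 -0.63 and interferon -0.0244. Of 26 lists, 13 passed camera, 3 with an estimated correlation and 24 with fry, which tests another hypothesis. The cause of the other changes was not tested. Lpl lost its call when any 1 wild-type library was left out (adjusted p up to 0.0598), as did the adipocyte list mean (0.122 to 0.152), and the X-linked premeiotic list without knockout replicate 2 (adjusted p = 0.0608) or 4 (0.0666). The X odds ratio for higher genes ranged from 2.00 to 3.06 under the alternatives. Whether the replicate numbers pair the samples stayed undecided: same-number correlations ran from -0.04 to 0.12, over 0.1 in 2 of 4 pairs, and 4 of 8 samples correlated best with their own number. With the replicate block 14161 genes were called (7520 higher, 6641 lower), and the macrophage list passed (adjusted p = 0.0331), as it did without knockout replicate 3 (0.0403). The TFIID list passed with no filter on low counts (adjusted p = 0.0470). In simulated counts with only 200 genes changed, 73.3% of 1.5-fold changes were recovered.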

Other observations

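The tests of this part were chosen after the result was seen, and the genes were named after their values were seen.

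All 13 tested mitochondrially encoded genes rose with TMM, by a median log2 fold change of 1.10, and with library size alone (1.90), while their median turned to -0.79 when libraries were scaled to the Sertoli list. Mt-co1 rose from 8832 to 18003 CPM and Mt-nd4 from 1848 to 4240 CPM. Nuclear genes of oxidative phosphorylation had a median of -0.55.

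Some genes rose by more than the mean level of the Sertoli cell list. With libraries scaled to that list, 1037 genes stayed higher, and 696 of them had a symbol, at least 5 CPM and no overlap between groups. The 1037 include Sertoli markers themselves, such as Clu (0.58), Shbg (0.55) and Cst12 (0.25). The Sertoli list median was 0.19 on that scale, so the count is not one of genes beyond these markers. On that scale Wnt4 was higher by a log2 fold change of 4.19, Testin by 2.67, Tnfrsf12a by 2.19, Nes, an intermediate filament gene, by 1.73, and Mapk13, a stress kinase, by 1.55.

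Spermatid transcripts did not vanish in the knockout. With TMM scaling the median round spermatid gene kept 7.85% and the median elongating spermatid gene 9.04% of its wild-type CPM. The round spermatid median of -3.67 on the log2 scale was -2.87 with library size alone and -5.56 with Sertoli scaling, so these shares depend on scaling. Prm1 stood at 372, 153, 196 and 571 CPM in knockout replicates 1 to 4 while Acrv1, a round spermatid gene, stood at 8.96, 9.74, 11.7 and 11.1 CPM. Carry-over of wild-type RNA would keep elongating and round spermatid transcripts in the wild-type ratio. This was measured in 2 ways: first as the difference of mean log2 list levels, where 4 of 4 knockout libraries lay over 3 SD from the wild type, and then, because a pseudocount compresses low values, as the log2 ratio of summed CPM, where 3 of 4 did. On both measures knockout replicates 2 and 3 lay below the wild type and knockout replicate 4 above it, at least 4.61 SD away, which argues against carry-over as the whole cause there. In knockout replicate 1 the measures disagreed (5.76 SD and 0.0782 SD), so it was taken separately after both were seen. For that library these measures did not settle whether carry-over was the whole cause. A partial share stays open. The lowest ratio of group means among 4345 well measured genes was 4.25% with TMM (Glipr1l1), an upper limit on a carried-over share in those means. By library, Glipr1l1 stood at 1.49, 4.30, 3.07 and 3.38 CPM in knockout replicates 1 to 4, against 66.1 to 75.6 CPM in the wild type. A few remaining spermatids may be the source of the rest, which was not tested.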
